A study of Mus musculus with 6 samples.

How the data were processed

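RNA sequencing libraries were made from total RNA of mouse alveolar epithelial type 2 preparations, isolated with TRIzol, with the KAPA stranded RNA-seq kit, per the labels' protocols. The series design assigns 3 mice to PBS and 3 to bleomycin, and groups and replicate numbers were taken from the sample titles. How the cells were isolated, the number, spacing and route of exposures, and the time of harvest are not given in the sources used here. HISAT2 and StringTie are named per the submitters' processing notes, with FastQC version 0.10.1 and the mouse build mm10, but the annotation and the settings are not given in the sources used here.

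The authors deposited one file per library with an FPKM value (a fragment count scaled by transcript length and by the library's mapped fragments) for each transcript, per the file headers. All 6 files list the same 24647 transcripts, each marked protein coding, of 13931 genes. How these transcripts were selected is not given in the sources used here. The files list 1 transcript of the mitochondrial genome and 11 of chromosome Y, 44 transcripts are at 0 in all 6 libraries, and 619 genes are below 1 FPKM in all 6. Of the transcript IDs, 21364 occur with the same version in GENCODE release M21, whose GRCm38 assembly is the mm10 build. Coordinates are printed as the files give them. The listed FPKM sum to between 253146 and 300697 per library, and this sum covers only the listed transcripts. Whole reads could not be recovered: among 1097 genes with 1 transcript, at most 19.1% of low values fell on a common step, so the sequencing depth and the counting error of each value are unknown, and no interval from counts is given. An exact 0 in these files can be a failed estimate, so library values are given where a named gene listed at 0 in a library is compared between groups.

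Transcript FPKM were summed by gene ID. Where 2 gene IDs share a symbol, which holds for 9 symbols, the symbol stands for the ID with the higher mean, and both were tested. Genes with 1 FPKM or more in at least 3 of the 6 libraries were tested, 12326 in all, on log2(FPKM + 1). Fold changes are differences of these log values, bleomycin minus PBS, and understate the change of low genes. The test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, group as the only term) with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had been written for TPM, with the same test on FPKM if the files held no TPM, and the files hold FPKM only. With 3 libraries against 3, an exact permutation test of one gene cannot reach p = 0.05, so every adjusted p here comes from limma, which pools the spread across genes.

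Before the data were examined, 45 gene lists (cell type markers, pathways and quality groups) were fixed. Lists with 5 or more tested members, 40 of them, were tested with limma's camera (preset correlation of 0.01, two-sided), which asks whether a list moved relative to all other genes, with adjustment over the 40 lists. The other 5 (basal cells, mast cells and basophils, mitochondrially encoded, sex-linked and histone genes) were too short. Camera with an estimated correlation and fry were alternatives. Counts of list members that passed are given after adjustment over all genes and adjusted over the list alone. They refer to tested members, called measured in the text, and leave out listed members below the filter. A gene could pass the filter through the 3 libraries of a single group.

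Genes named in the text follow a rule fixed at the same time. It takes the 10 largest increases and the 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap between the groups' values, leaving out numbered gene models and antigen receptor segments. It adds up to 4 members with the smallest adjusted p of each list, and Sftpc, Sftpb, Sftpa1, Abca3, Lamp3, Ager, Krt8, Cdkn1a, Mfn1, Mfn2, Col1a1, Ptprc and Pecam1 in any case. Some genes that this rule takes are not reported here. Of 12326 tested genes, 5378 (43.6%) had no overlap between the groups' values, against 10% by chance.

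The gene test was tested on simulated data with the spread of the real genes and 200 changed genes among 12326. For the comparison of bleomycin with PBS it recovered 77.5% of genes changed by 2 on the log2 scale, with 6.63% false calls, and 0% of genes changed by 1. The real comparison called 2776 genes, so recovery in the real data can differ from that with 200 changed genes. The list test recovered 5 of 5 simulated lists of 20 genes moved by 1 and called none of the 35 unchanged ones. Its genes were simulated without correlation, so this gives no error rate for lists of correlated members. In the real lists the estimated correlations reached 0.965. Alternatives covered the pseudocount (0.1 and 5), the filter (none and 5 FPKM), the scaling of libraries, the transcript sum, the variance model, library weights, the replicate number as a block and each library left out.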

Results

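Transcript abundance was measured by RNA sequencing in cells prepared from the lungs of 6 C57BL/6 mice as alveolar epithelial type 2 cells (AT2 cells), the cells that make and store pulmonary surfactant. There were 3 libraries from mice given PBS and 3 from mice given bleomycin, a DNA-cleaving drug used to injure the rodent lung. Each library came from its own mouse, and the labels give repeated exposure and a bleomycin dose of 1 U/kg. The deposited values are FPKM, so the number of reads behind each value is unknown. The 24647 listed transcripts, the same in all 6 libraries, fall into 13931 genes, and their FPKM sum to between 253146 and 300697 per library. Across genes, the log2 values of 2 PBS libraries correlated with r of 0.928 to 0.934 and those of 2 bleomycin libraries with r of 0.911 to 0.930. Between a PBS and a bleomycin library r was 0.773 to 0.837. These r values are taken across genes, which are not independent replicates.

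The comparison of bleomycin with PBS asks which transcripts of the AT2 preparations differ after repeated bleomycin exposure. In the list of surfactant and identity genes of AT2 cells 14 of 21 genes fell and none rose, in the lipid synthesis lists 24 of 69 fell and 2 rose, and in the fibroblast and smooth muscle list 6 of 19 fell and none rose. In the leukocyte lists 69 of 85 genes rose, and in the endothelial list 15 of 17, while none fell. Those of these lists that were long enough to test passed camera with a preset correlation, but not with an estimated correlation (adjusted p of 0.249 to 0.311). Sftpc, the gene of surfactant protein C, fell from 16103 ± 3941 FPKM to 4569 ± 1920 (mean ± SD, n = 3 each), while Lck, a kinase of T cells, rose from 0.292 ± 0.0442 to 45.2 ± 3.81. Of 12326 genes tested with limma, 1871 rose and 905 fell at an adjusted p under 0.05, and 1334 and 533 of these changed at least 2-fold. With each library scaled to the same median, which moved the median log2 fold change of all tested genes from 0.09 to -0.07, the split was 1475 higher and 1412 lower. With quantile normalization it was 1431 and 1441, with a median of -0.08. Rises made up 67.4% of the calls without scaling, 51.1% with equal medians and 49.8% with quantile normalization. Without PBS replicate 1, 2 or 3, 473, 514 and 457 genes fell, and without bleomycin replicate 1 or 2, 513 and 508, against 905 with all libraries. Without PBS replicate 3, bleomycin replicate 1 or bleomycin replicate 2, 1782, 1843 and 1825 genes changed in all, against 2776.

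The largest rises by the fixed rule were mostly of leukocyte genes. Jchain, which joins secreted immunoglobulin subunits, rose by 6.18 ± 0.35 (log2 fold change ± SE of log2(FPKM + 1), limma adjusted p = 0.000158), from 2.82 ± 0.368 to 301 ± 165 FPKM (mean ± SD, n = 3). Ptprc, which encodes the pan-leukocyte antigen CD45, rose by 5.59 (adjusted p = 0.00216), Gzma, a granule protease of cytotoxic lymphocytes, by 5.42, and Ccl5, a chemokine of T cells, by 5.34. Cd69, Lck, Laptm5, Dusp2 and Itgb2 rose by 5.16, 5.16, 5.14, 5.09 and 4.97. Cldn5, a tight junction gene of endothelium, was listed at 0 in all 3 PBS libraries and at 68.1, 146 and 75.6 FPKM in bleomycin replicates 1, 2 and 3. It has 1 exon, a class of genes whose listed zeros are treated in the closing section. Among the largest falls, Bex4 and Bex2, a pair of nearby genes on chromosome X, changed by -3.87 and -3.82. Ppp1r1b, Cxcl14, Acoxl, Loxl1, Rnf139 and Rnase4 changed by -3.01, -2.98, -2.88, -2.82, -2.82 and -2.81. Lyz1, a lysozyme gene, and Prrg3 changed by -2.60 and -2.63, with adjusted p of 0.03 and 0.0299. The call of Lyz1 was lost without PBS replicate 2 or any 1 bleomycin library (adjusted p 0.0521 to 0.0787), and that of Prrg3 without PBS replicate 1 or 3 or bleomycin replicate 1 or 2 (0.0885 to 0.0925).

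In the AT2 surfactant and identity list, 14 of 21 measured genes fell and none rose (18 fell adjusted over the list alone). The list's median log2 fold change was -1.66, and it fell relative to other genes (limma camera, adjusted p = 1.21e-09, and adjusted p = 0.262 with an estimated correlation). Abca3, the lipid transporter of lamellar bodies (ENSMUSG00000024130.15, mm10 chromosome 17, 24352023 to 24410201), fell from 207 ± 26 to 53.1 ± 13.1 FPKM, a change of -1.97 ± 0.23 (adjusted p = 0.00166). Sftpb, the gene of surfactant protein B, changed by -1.82 ± 0.26 (adjusted p = 0.0043), Sftpa1, of surfactant protein A, by -1.66 (adjusted p = 0.013), and the lamellar body gene Lamp3 by -1.93 (adjusted p = 0.0131). Muc1 and Ppp1r14c changed by -1.89 and -2.10. Sftpc (ENSMUSG00000022097.3, mm10 chromosome 14, 70520941 to 70524081) changed by -1.90 ± 0.48 with an adjusted p of 0.0349. The 3 PBS values of Sftpc lay between 13393 and 20624 FPKM and the 3 bleomycin values between 2356 and 5805. Its adjusted p was 0.0968, 0.0833, 0.0699, 0.0687 and 0.0838 without PBS replicate 1, 2 or 3 or bleomycin replicate 1 or 2. In the same bleomycin libraries the T and NK cell list had a median log2 fold change of 3.85 and the endothelial list one of 2.34.

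**Figure D1:**
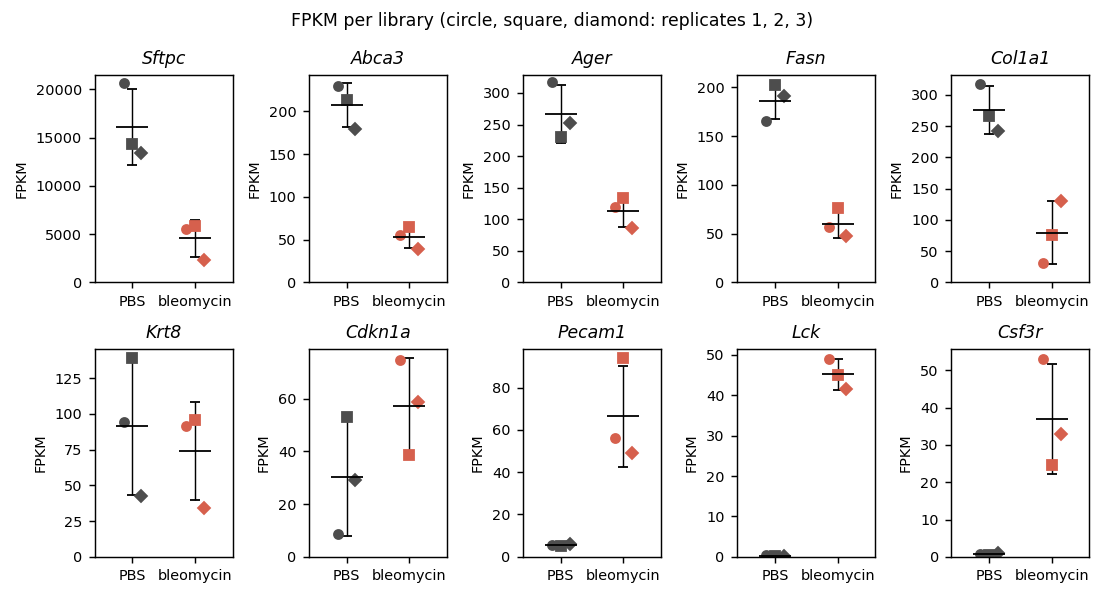
FPKM of 10 named genes in each library, with the FPKM axis starting at 0 and one scale per gene. Circles, squares and diamonds are replicates 1, 2 and 3 of PBS (grey) or bleomycin (red), whose shared numbers are not said to mark pairs, and the long dash with its bar is the mean ± SD (n = 3). Sftpc, Abca3, Ager, Fasn and Col1a1 lie lower and Pecam1, Lck and Csf3r higher in all 3 bleomycin libraries, while the values of Krt8 and Cdkn1a overlap between groups.

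Among other epithelial genes, AT1 markers, of the flat cells of gas exchange, fell as a list (adjusted p = 0.011, and adjusted p = 0.262 with an estimated correlation), with 5 of 22 lower, 1 higher and 16 that did not pass. Adjusted over the list alone, 6 fell and 1 rose. Ager, the best known of them, fell from 267 ± 45.5 to 113 ± 24.8 FPKM (-1.24 ± 0.23, adjusted p = 0.0117), Cldn18 changed by -1.36, and the basement membrane collagen genes Col4a4 and Col4a3 by -1.27 and -1.05. The list of injury-associated transitional epithelium did not pass (adjusted p = 0.465), with 1 of 23 genes higher and 2 lower, the same counts as adjusted over the list alone. Its member Plaur, the urokinase receptor gene, rose by 1.84, and Ctgf and Nupr1 changed by -1.79 and -0.90. The call of Nupr1 was lost without PBS replicate 1 (adjusted p = 0.052), PBS replicate 3 (0.0597) or bleomycin replicate 2 (0.0622). Krt8, a keratin gene of that state, measured 91.8 ± 48.4 FPKM with PBS and 73.7 ± 34.3 with bleomycin (log2 fold change -0.29 ± 0.55, limma adjusted p = 0.739). The list of club and secretory airway cells did not pass either (adjusted p = 0.465), with 2 of 14 genes higher and 2 lower, the same adjusted over the list alone. The 2 that fell were Sftpa1 and Aldh1a7 (-1.10), the latter with its call lost without any 1 library but PBS replicate 3 (adjusted p 0.0656 to 0.101). The 2 that rose were the secreted airway proteins Bpifa1 (1.88) and Scgb3a1 (1.31), the second of which did not pass without bleomycin replicate 1 (adjusted p = 0.0727) or bleomycin replicate 2 (0.0677). Ciliated airway cell genes rose as a list (adjusted p = 0.00425, and adjusted p = 0.577 with an estimated correlation), with 3 of 14 higher, or 5 adjusted over the list alone, and a median log2 fold change of 0.89. The 3 were Dnah5 (0.86), Dnah9 (0.80) and Sec14l3 (0.70), and each call was lost without PBS replicate 2 or bleomycin replicate 1 or 2. The calls of Dnah5 and Sec14l3 were also lost without PBS replicate 1 and that of Dnah9 without PBS replicate 3 (adjusted p between 0.0703 and 0.0933 in these fits). Of 5 tested neuroendocrine genes, from 8 listed, 2 rose, Calca and Pcsk1, both from means under 2 FPKM, and the list did not pass (adjusted p = 0.261). Both calls were lost without PBS replicate 3 or bleomycin replicate 1 or 2, that of Calca also without PBS replicate 1 and that of Pcsk1 also without PBS replicate 2 (adjusted p 0.0754 to 0.101). Of 8 listed basal cell genes only 3 passed the filter and were tested, Aqp3, Dapl1 and Krt15, while Krt5, Krt14 and Trp63 did not pass it. Aqp3 rose by 1.88, from a PBS mean of 0.284 FPKM. Dapl1 was listed at 0 in all 3 PBS libraries and at 15.1, 12.1 and 4.05 FPKM with bleomycin, and Krt15 had a limma adjusted p of 0.248.

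Over the 7 leukocyte lists, 69 of 85 measured genes rose and none fell (74 rose and 1 fell adjusted over these lists alone), and the median over genes of the mean FPKM was 1.07 with PBS and 16.2 with bleomycin. All 16 measured T and NK cell genes rose (all 16 adjusted over the list alone, adjusted p of the list 2.62e-14, and adjusted p = 0.262 with an estimated correlation), among them Lck, Cd3d (4.77) and Cd3e (4.08). Cd8a, of the same list, was at 0.138, 0 and 0.0693 FPKM in PBS replicates 1, 2 and 3 and at 7.96, 7.79 and 6.88 with bleomycin. All 11 neutrophil genes rose (11 adjusted over the list alone, list adjusted p = 3.49e-08, and adjusted p = 0.249 with an estimated correlation), with the receptor gene Csf3r up from 0.758 ± 0.341 to 36.9 ± 14.7 FPKM. Of 11 B and plasma cell genes 10 rose (10 higher and 1 lower adjusted over the list alone, list adjusted p = 4.8e-07, and adjusted p = 0.262 with an estimated correlation), including Cd79a (4.25) and Blk (3.67). Cr2, also among them, was at 0, 0.272 and 0.186 FPKM in PBS replicates 1, 2 and 3 and at 8.73, 5.80 and 5.34 with bleomycin. Of 17 alveolar macrophage genes 12 rose (15 adjusted over the list alone, list adjusted p = 3.4e-07, and adjusted p = 0.249 with an estimated correlation), with Itgax, Mrc1, Abcg1 and Car4 higher by 3.81, 3.09, 2.87 and 2.74. Of 19 genes of monocytes and recruited macrophages 11 rose (11 adjusted over the list alone, list adjusted p = 0.000784, and adjusted p = 0.311 with an estimated correlation), such as Ccr2 (3.51), Csf1r (3.29) and Adgre1 (3.28). Ms4a7, of the same list, was listed at 0 in each PBS library and at 3.21, 2.99 and 3.97 FPKM with bleomycin. Of 8 tested dendritic cell genes, from 11 listed, 6 rose (8 adjusted over the list alone, list adjusted p = 0.000172, and adjusted p = 0.249 with an estimated correlation), with Itgae, Flt3, Ccr7 and Batf3 higher by 2.45, 2.03, 1.59 and 1.37. Of 6 listed genes of mast cells and basophils only 3 passed the filter, too few for a list test. These, Gata2, Kit and Cma1, rose by 2.87, 2.77 and 1.68, with Cma1 at a bleomycin mean of 3.04 FPKM. Whether these transcripts came from mast cells and basophils was not tested, and the endothelial list had a median of 2.34 in the same libraries.

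Endothelial genes rose as well, with 15 of 17 higher (16 adjusted over the list alone) and a list adjusted p of 1.21e-09, or an adjusted p = 0.262 with an estimated correlation. Pecam1, which encodes the endothelial adhesion molecule CD31, rose from 5.66 ± 0.601 to 66.4 ± 24.1 FPKM (3.28 ± 0.26, adjusted p = 0.000383), Vwf by 3.71 and Calcrl by 3.65. Erythroid genes, a mark of blood in the preparation, rose as a list (adjusted p = 0.0165, and adjusted p = 0.524 with an estimated correlation), with 3 of 6 higher, or 6 adjusted over the list alone. Without PBS replicate 1 that list had an adjusted p of 0.055. The alpha globin gene Hba-a1 measured 4.61, 109 and 5.77 FPKM in PBS replicates 1, 2 and 3 and 249, 424 and 246 with bleomycin. Hba-a1 and Hbb-bt passed with adjusted p of 0.0388 and 0.0493, and both calls were lost without any 1 library but PBS replicate 2 (adjusted p 0.0785 to 0.137). Near-identical globin copies share reads, so the split between copies is uncertain.

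Of 19 measured fibroblast and smooth muscle genes 6 fell and none rose (11 fell adjusted over the list alone), with a list median of -1.35 (list adjusted p = 2.25e-06, and adjusted p = 0.262 with an estimated correlation). Col1a1, the gene of the main fibrillar collagen chain (ENSMUSG00000001506.10, mm10 chromosome 11, 94936224 to 94953042), fell from 276 ± 38.6 to 79.4 ± 50.2 FPKM (-2.0 ± 0.49, adjusted p = 0.0317). Col3a1 and Col1a2 both changed by -1.90, Npnt by -1.59 and Tagln by -1.35. Without PBS replicate 1 the adjusted p of Col1a1, Col1a2 and Col3a1 were 0.0933, 0.0721 and 0.0647, without PBS replicate 3 they were 0.0758, 0.0669 and 0.0669, and without bleomycin replicate 2 they were 0.0746, 0.0522 and 0.053. Without PBS replicate 2 those of Col1a1, Col1a2 and Npnt were 0.0798, 0.055 and 0.0749. Npnt also missed the threshold without PBS replicate 3 (0.0864) or bleomycin replicate 2 (0.0639). None of 8 mesothelial genes passed, and the list did not either (adjusted p = 0.699, with a median of 0.18 while the test pointed down). The list of extracellular matrix and profibrotic ligands fell (adjusted p = 0.0122, and adjusted p = 0.262 with an estimated correlation), although 3 of its 27 genes rose beside 6 that fell (5 and 8 adjusted over the list alone). Spp1, the osteopontin gene, and Tgfb1, of the cytokine TGF-beta 1, rose by 4.07 and 1.99, while Ctgf and the laminin gene Lamb3 changed by -1.79 and -1.26. Lamb3 had an adjusted p of 0.0601 without PBS replicate 1 and 0.0607 without PBS replicate 2. The list of the epithelial to mesenchymal transition did not pass (adjusted p = 0.339). Its members S100a4 and Col1a1 changed by 3.25 and -2.0, and its epithelial member Epcam measured 47.5 ± 5.58 FPKM with PBS and 23.7 ± 9.69 with bleomycin (limma adjusted p = 0.0634).

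**Figure D2:**
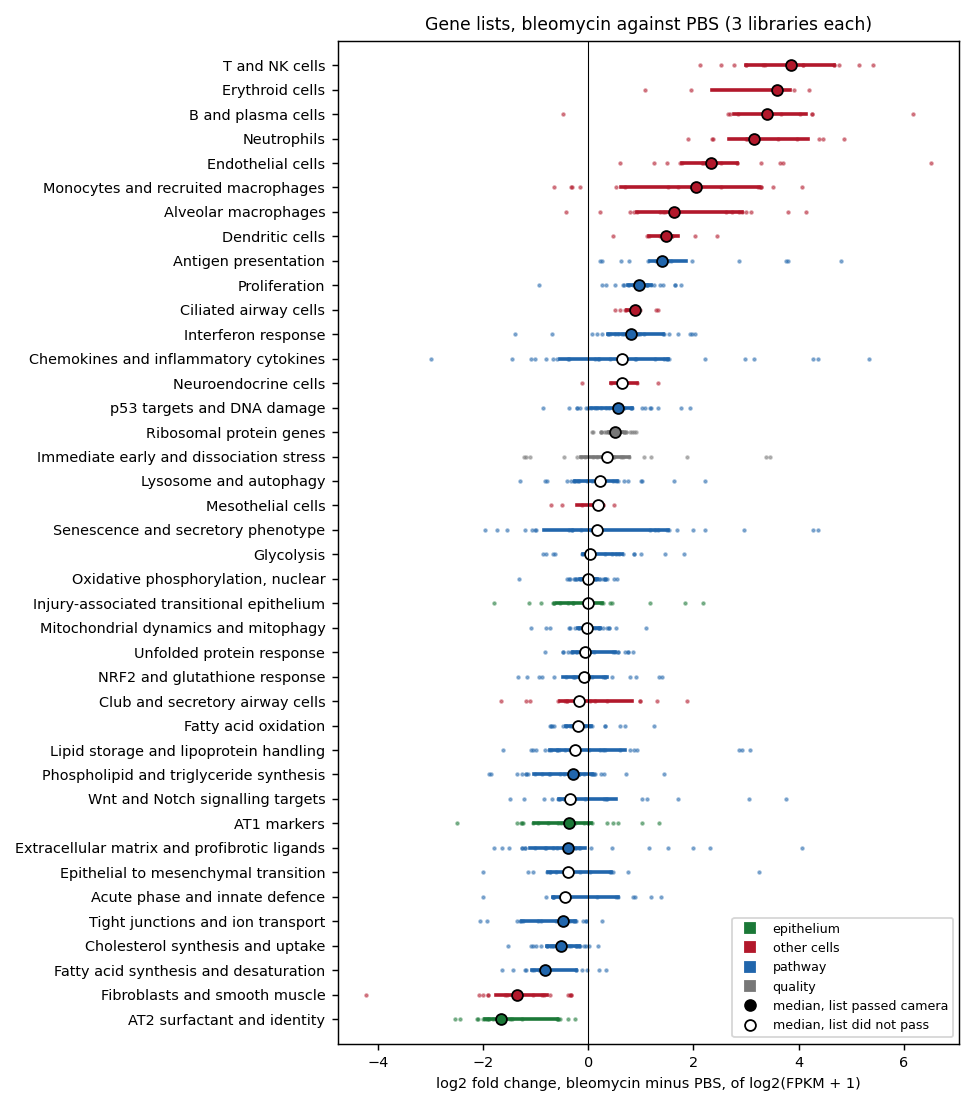
Log2 fold change (bleomycin minus PBS, of log2(FPKM + 1), 3 libraries each) of the members of the 40 tested gene lists, in order of the list median. Small points are genes, the bar is the interquartile range and the large point is the median, filled where the list passed camera with the preset correlation and open where it did not. T and NK cell genes lie highest, with a median of 3.85, and AT2 genes lowest, with a median of -1.66.

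Over 3 lists of lipid synthesis, 24 of 69 measured genes fell and 2 rose (26 and 2 adjusted over these lists alone). In cholesterol synthesis and uptake 9 of 24 fell and none rose (9 adjusted over the list alone, list adjusted p = 5.65e-05, and adjusted p = 0.249 with an estimated correlation). Its members Acat2, Fdft1 and Lss, all enzymes of the pathway, changed by -1.09, -1.0 and -0.78. Leaving out single libraries ended these calls, for Lss any PBS library or bleomycin replicate 2 (adjusted p 0.0539 to 0.0705). For Fdft1 these were PBS replicate 2 and bleomycin replicates 1 and 2 (0.0586 to 0.074), and for Acat2 PBS replicates 2 and 3 (0.0512 and 0.0517). In fatty acid synthesis and desaturation 5 of 17 fell and none rose (7 adjusted over the list alone, list adjusted p = 0.000395, and adjusted p = 0.249 with an estimated correlation). Fasn, the fatty acid synthase gene (mm10 chromosome 11, 120805846 to 120824547), fell from 186 ± 18.9 to 60.3 ± 14.9 FPKM (-1.63 ± 0.21, adjusted p = 0.00285). Acaca, of the carboxylase one step before it, changed by -1.43, the transcription factor gene Srebf1 by -1.18 and the desaturase gene Fads2 by -1.08, the last with an adjusted p of 0.0544 without PBS replicate 3. In phospholipid and triglyceride synthesis 10 of 28 fell and 2 rose (10 and 2 adjusted over the list alone, list adjusted p = 0.00097, and adjusted p = 0.262 with an estimated correlation). Pcyt1a, the rate-limiting enzyme of phosphatidylcholine synthesis, changed by -1.89 ± 0.30, and Gpam, Lpin3 and Pgs1 by -1.84, -1.36 and -1.15. In these libraries the median log2 fold change of the AT2 list was -1.66. Fatty acid oxidation did not pass as a list (adjusted p = 0.0729), with Ucp2 higher by 1.24 and Ppargc1b by 0.70, but the call of Ppargc1b was lost without any 1 PBS library or bleomycin replicate 2 (adjusted p 0.0569 to 0.0679). Lipid storage and lipoprotein handling did not pass (adjusted p = 0.465), with 5 of 23 genes higher and 4 lower (6 and 5 adjusted over the list alone). Abcg1 and Scarb1, of cholesterol transport, rose by 2.87 and 0.94, and Soat1 changed by -1.04. Hilpda, listed at 0 in PBS replicate 2, was at 0.582 and 0.466 FPKM in the other two PBS libraries and at 17.1, 3.75 and 15.3 with bleomycin.

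Targets of p53, the transcription factor activated by DNA damage, passed narrowly as a list (adjusted p = 0.0415, and adjusted p = 0.262 with an estimated correlation), with 9 of 29 genes higher and none lower, the same adjusted over the list alone. Psrc1, Trp53inp1, Tnfrsf10b and Bax rose by 1.19, 1.08, 1.03 and 0.82, the last with its call lost without PBS replicate 2 or 3 or bleomycin replicate 1 or 2 (adjusted p 0.0612 to 0.067). The list of p53 targets and DNA damage did not pass in 5 of the 6 fits that left out 1 library (adjusted p of 0.1 and 0.0706 without PBS replicates 1 and 3, and of 0.0532, 0.0506 and 0.0714 without bleomycin replicates 1, 2 and 3), nor with the filter at 5 FPKM (0.494). Cdkn1a, the cell cycle inhibitor p21 and a p53 target, measured 30.3 ± 22.3 FPKM with PBS and 57.4 ± 18.2 with bleomycin (1.17 ± 0.62, limma adjusted p = 0.225). Senescence and secretory phenotype genes did not pass as a list (adjusted p = 0.592). Of 26, 8 rose and 3 fell (10 and 6 adjusted over the list alone). The members with the smallest adjusted p were Lmnb1, Tgfb1, Il1b and Tnf, which rose by 1.69, 1.99, 4.37 and 2.22. Lmnb1 encodes lamin B1, whose loss marks senescent cells, and the other 3 are secreted cytokines also made by leukocytes. Proliferation genes rose as a list (adjusted p = 1.34e-05, and adjusted p = 0.445 with an estimated correlation), with 14 of 25 tested genes, from 32 listed, higher and none lower (21 and 1 adjusted over the list alone). Mki67 rose from 0.863 ± 0.495 to 4.95 ± 2.26 FPKM, and the replication licensing genes Mcm3, Mcm5 and Mcm2 rose by 1.42, 1.36 and 1.12. Without PBS replicate 1 the adjusted p of Mki67 was 0.0502. Ptprc rose by 5.59 and Pecam1 by 3.28 in the same bleomycin libraries. The unfolded protein response did not pass (adjusted p = 0.488), with Asns alone of 25 genes higher (0.76, its call lost without any 1 library but PBS replicate 1, with adjusted p 0.0693 to 0.102), and with 0 adjusted over the list alone.

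Interferon response genes rose as a list, 13 of 25 higher and none lower (14 adjusted over the list alone, list adjusted p = 9.09e-05, and adjusted p = 0.249 with an estimated correlation). Oas1a, Zbp1, Oas2 and Irf7 rose by 2.02, 1.97, 1.44 and 1.43. Antigen presentation genes rose, 15 of 18 (16 adjusted over the list alone, list adjusted p = 3.49e-08, and adjusted p = 0.249 with an estimated correlation). Ctss, a protease of antigen processing, rose by 4.82, and the class I regulator Nlrc5 by 2.87. The class I genes H2-Q6 and H2-Q7 rose by 3.80 and 3.77, but they are close copies that can share reads. In the chemokine and inflammatory cytokine list 11 of 26 rose and 4 fell (12 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.241). Ccl5, Il1b, Ccl4 and Tnf rose by 5.34, 4.37, 2.98 and 2.22. The T and NK cell and neutrophil lists, whose cells also express many of these genes, had medians of 3.85 and 3.15. Acute phase and innate defence genes did not pass as a list (adjusted p = 0.199), with 2 of 17 higher and 1 lower, the same adjusted over the list alone. Chil1 fell from 823 ± 71.2 to 214 ± 67.4 FPKM, and Slpi and Orm1 rose by 1.38 and 1.20. Both calls were lost without PBS replicate 2 or 3, and that of Orm1 also without bleomycin replicate 1 or 2 (adjusted p 0.0645 to 0.122).

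Mfn1 and Mfn2, whose products fuse mitochondria, measured 9.88 ± 1.04 and 11.2 ± 3.61 FPKM with PBS and 9.84 ± 2.6 and 12.3 ± 3.65 with bleomycin (log2 fold changes -0.03 ± 0.21 and 0.13 ± 0.30, limma adjusted p = 0.941 and 0.786). Of 25 genes of mitochondrial dynamics and mitophagy, Tomm20 rose by 0.53 and Optn and Bnip3 changed by -1.09 and -0.80, 2 lower and none higher adjusted over the list alone, and the list did not pass (adjusted p = 0.465). The call of Tomm20 was lost in each fit that left out 1 library (adjusted p 0.0629 to 0.0959). Of 36 nuclear genes of oxidative phosphorylation 1, Cox6a1, fell (-1.32, and adjusted p of 0.0752, 0.0591 and 0.0592 without PBS replicate 1, 2 or 3), with 0 adjusted over the list alone and a list adjusted p of 0.538. In glycolysis 6 of 22 rose and none fell (7 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.538). The members with the smallest adjusted p, Slc16a3, Eno1, Gapdh and Slc2a1, rose by 1.83, 1.46, 0.87 and 0.87. Slc2a1 had an adjusted p of 0.052 without bleomycin replicate 2. The NRF2 and glutathione list did not pass (adjusted p = 0.592), with Fth1, Gsr and Slc7a11 higher by 1.41, 1.34 and 0.91 and Cat, the catalase gene, changed by -1.33, the same 3 and 1 adjusted over the list alone. Fth1 had an adjusted p of 0.0513 without PBS replicate 2, and Slc7a11 one of 0.151 with quantile normalization. Of 27 lysosome and autophagy genes 3 rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.98), with Gla higher by 2.22.

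Among the remaining lists, tight junction and ion transport genes fell (adjusted p = 9.36e-05, and adjusted p = 0.311 with an estimated correlation), with 3 of 20 lower and none higher (6 adjusted over the list alone). The 3 were Slc26a9 (-2.05), Cldn18 (-1.36) and the sodium channel gene Scnn1a (-1.29), the last with adjusted p of 0.0597 and 0.0589 without PBS replicates 1 and 2. In the Wnt and Notch list 5 of 20 rose and 4 fell (5 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.576). Its largest rises, Tcf7 (3.77) and Lef1 (3.05), are of transcription factors that T cells also express, Dll4, a Notch ligand of endothelium, rose by 1.71, and Nkd1 changed by -1.22. In the list of Immediate early and dissociation stress 1 of 21 genes passed, Klf2 (1.87), also 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.656), but its adjusted p was 0.0222 without PBS replicate 2, with a median of 0.70. In the PBS libraries left in that fit, its members Junb (replicate 3), Ier2 and Hspa1a (replicate 1) were listed at 0. All have 1 exon, and these zeros can be failed estimates. Ribosomal protein genes rose as a list (adjusted p = 0.000172, and adjusted p = 0.577 with an estimated correlation), with 5 of 35 higher and none lower, the same adjusted over the list alone. Rpl22, Rpl13, Rpsa and Rps24 rose by 0.91, 0.88, 0.84 and 0.80. The calls of Rpl13, Rpsa and Rps24 were lost without PBS replicate 2 or bleomycin replicate 1 or 2, that of Rpl13 also without PBS replicate 1 and the other two also without PBS replicate 3 (adjusted p 0.0517 to 0.102). Of the lists too short to test, none of 3 histone and 4 Y-linked genes passed, and the 1 listed mitochondrially encoded gene, mt-Co1, measured 6846 FPKM in PBS replicate 1 against 14.5 and 14.3 in PBS replicates 2 and 3 and 0.98, 1.26 and 0.831 with bleomycin.

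In all, 22 of the 40 tested lists passed, 14 higher and 8 lower, by camera with a preset correlation. With an estimated correlation 0 passed, while 24 passed limma's fry, which does not compare a list with other genes. Lists whose estimated correlation lay below the preset 0.01 also had higher adjusted p with it, so the 0 does not measure correlation between members alone. Each value is that of a whole preparation, whatever its mix of cell types.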

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

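The alternatives equal totals, single transcripts, leaving out genes with listed zeros and leaving out markers of other cell types were chosen after seeing the data, and the others before the data were examined. All counts refer to the comparison of bleomycin with PBS, and the calls of limma and camera at an adjusted p under 0.05. With all libraries 2776 genes changed (1871 higher, 905 lower) and 22 lists (14 higher, 8 lower). Leaving out 1 library gave 1782 to 2630 changed genes, 1317 to 1757 higher and 457 to 873 lower, of which 1689 to 2217 changed genes were shared with the full set, and 20 to 23 lists. The fewer residual degrees of freedom (3 in place of 4) belong to the construction of these fits. The lower genes numbered 1412 with equal medians and 1441 with quantile normalization, of which 905 and 892 were shared with the main call, so these scalings added falls, 533 with a 2-fold minimum and 1432 at an adjusted p under 0.1. The other alternatives moved no gene count by more than 1.5 times apart from the replicate block. With the replicate block 1922 genes changed, of which 1833 were shared, and 563 were lower, with 2 residual degrees of freedom. The labels do not say whether a shared number pairs libraries. Same-numbered libraries' deviations correlated with r of -0.0043, 0.017 and 0.039 across genes, and differently numbered ones with r of -0.035 to 0.021. Not every library correlated best with its own number, but such small values cannot exclude a pairing. With an estimated correlation 0 lists passed, 0 higher and 0 lower, where limma's fry called 24 of 40 lists. Fry did not pass 3 lists that camera had called with the preset correlation. These were extracellular matrix and profibrotic ligands (fry adjusted p = 0.12), ciliated airway cells (0.0811) and erythroid cells (0.0645). In the 40 lists the estimated correlations between members reached 0.965. Fatty acid oxidation, with an estimated correlation of 0.00737, below the preset 0.01, also had a higher camera adjusted p with it (0.262 against 0.0729). Fry called Wnt and Notch signalling targets higher (adjusted p = 0.0143), opposite to camera's direction, which had not passed. The median log2 fold change of that list was -0.34 but its mean was 0.21, and the cause was not tested. Without an estimated correlation, the lists of p53 targets, fatty acid oxidation, erythroid cells and immediate early genes, and under fry 8 lists, crossed the threshold under 1 or more alternatives, and no called list or named gene changed sign. Of up to 190 named genes, a left-out library ended 8 to 33 calls, the replicate block 13, quantile normalization 11 (that of Sftpc, the top gene of 5 libraries, by construction) and any other alternative at most 8. FPKM as the unit is the main analysis itself and the count alternatives need counts, so these gave no separate values. The robust and trend options enter the gene test only and gave no separate values for lists. The depth is unknown, and the listed sums differ between libraries by less than 1.5 times.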

Other observations

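The tests of cell type mix, of even change in the type 2 list, of lipid genes, of zeros beside high values in the same group and of other splits were chosen after the values they rest on had been seen, as were the genes of the next paragraph outside the fixed rule. The test of single exons over all genes listed at 0 was written down before its result was known, but was prompted by a few of the genes it covers.

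The 3 bleomycin libraries differed among themselves in single genes, macrophage genes among them. Bleomycin replicate 3 had 651 FPKM of Gpnmb, against 15 and 14.3 in replicates 1 and 2, 53.9 of Trem2 against 8.11 and 4.79, 715 of Lgals3 against 165 and 100.4, 71.7 of Fabp4 against 9.65 and 6.07, and 1082 of the cathepsin gene Ctsd against 325 and 318. Other macrophage genes did not follow: Itgax was at 31.3, 28.6 and 28.1 FPKM in replicates 1, 2 and 3 and Mrc1 at 20.04, 16.7 and 13.7. Chil3, an alveolar macrophage gene, went the other way, with 358 and 251 FPKM in replicates 1 and 2 and 135 in replicate 3. Bleomycin replicate 1 had 3508 FPKM of the lysozyme gene Lyz2, against 618 and 463 in replicates 2 and 3, and 105 of the fibroblast gene Inmt, against 812 and 945. The PBS libraries differed too. PBS replicate 1 had 9716 FPKM of the club cell gene Scgb1a1, against 2419 and 2011 in replicates 2 and 3, and PBS replicate 2 had 236 of the stress gene Atf3, against 19.7 and 10.7 in replicates 1 and 3, and 771 of Fos against 372 and 286.

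The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split changed 2776 genes and was 1 of 10 as large, with at most 2 genes in any other split. It changed 22 lists, again 1 of 10, with at most 21 in any other split. Each of the other splits sets 2 PBS libraries and 1 bleomycin library against 1 and 2, so part of the difference between the groups stays in it. The rest widens the spread within each side, which holds down the genes called, so their small counts are no separate support for the real split. Camera with the preset correlation still called 9 to 21 lists in these splits, beside 0 to 2 genes.

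Of the type 2 cell genes 14 of 21 fell, while 69 of 85 leukocyte and 15 of 17 endothelial genes rose. A lower share of type 2 cells, with all other cell types in fixed proportion, would raise the markers of those types alike. The median of the T and NK list, however, lay 5.21 ± 0.42 (log2) above that of the fibroblast list. Leukocyte and endothelial RNA added to an otherwise fixed mix would lower the rest alike, but the ciliated median lay 2.55 ± 0.24 above the type 2 median. Both ± values are SE from resampling list members. They treat correlated genes as independent and hold no spread between mice. In PBS 0 of the 16 T and NK genes and 6 of the 17 endothelial genes had means of 5 FPKM or more, against 15 and 16 with bleomycin (most abundant: Gzma, Nkg7 and Cd3g, and Cldn5, Pecam1 and Calcrl), and no T and NK or endothelial member was in another list, so cells of these types in the bleomycin preparations are a candidate source, which a CD45 or CD31 depletion, not described in the sources used here, would remove. Fewer type 2 cells with fixed transcript levels per cell and lower levels per cell cannot be told apart. Type 2 genes lay on both sides of the list mean, but 0 of 21 passed as lower than it and 0 as higher (limma, adjusted over the list). Their changes spread by an SD of 0.71 against a median SE of 0.30, and 5 of the 21 genes are in other lists.

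Beside them 24 of 69 genes of lipid synthesis fell and 2 rose. Fewer type 2 cell transcripts in the mix may account for the falls, but the values do not decide it. Of 68 lipid genes outside the type 2 list, 0 lay below that list's median by more than 2 standard errors, where 3 would have argued against it. The fold changes had been seen when this bound was set. The 69 lipid genes had a median log2 fold change of -0.54, against -1.66 for the type 2 list. A fall per cell smaller than that of the type 2 list would also give 0, so the 0 is no support for fewer type 2 cell transcripts. A lower lipid synthesis per type 2 cell after bleomycin stays open and was not tested, since no value here is per cell.

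Of the 6159 genes with 10 FPKM or more in at least 2 libraries, 73 were at exactly 0 in others, 46 of them in 1 library and 27 in 2 to 4, such as Junb in PBS replicate 3 (354 and 508 FPKM in the other two PBS libraries), Ier2 in PBS replicate 1 (247 and 130 in the others) and Hnrnpa0 in bleomycin replicate 2 (98.2 and 80.1 in the others), all named after their values were seen. Genes with 1 exon made up 41 of these 73 (56.2%) but 20 of the other 6083 with a known number of exons (0.329%; odds ratio 380, 95% interval 195 to 763, Fisher's exact test, two-sided, p = 4.76e-70). Where the gene was at 0 in 1 library of a group and at 10 FPKM or more in the other two, 25 of 28 genes had 1 exon (89.3%), against 36 of the other 6128 (Fisher's exact test, two-sided, p = 8.54e-50). Failed estimates for genes with a single exon are therefore a candidate explanation for the zeros of these 25 genes, while a zero in each library of a group, as for Cldn5 in PBS, can also be a low level. Of the 32 genes with more exons, 24 had their zeros in a group with all 3 values under 2 FPKM, where a zero can be a low level, and the zeros of the other 8 stay unexplained.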
